A study of Haplochromis burtoni with 44 samples.

How the data were processed

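Whole brains of 44 female *Astatotilapia burtoni* (*Haplochromis burtoni* in the labels) were measured by RNA sequencing of polyadenylated RNA, with 1 library per fish. RNA was extracted with an automated magnetic-particle kit (Maxwell LEV simplyRNA) with DNase treatment, and libraries were made after oligo(dT) selection with random hexamer priming, per the labels' protocols. No step that marks the strand is described there, so reads of overlapping genes on opposite strands may not have been separated. For 2 of the 44 libraries the labels record 2 sequencing runs, and each has 1 column in the deposited count table.

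The tools named per the submitters' processing notes are Trim Galore 0.6.4, FastQC 0.11.3, STAR 2.5.3 and StringTie 1.3.4, without roles or settings, and StringTie is recorded as 1.3.4b per the file headers. The genome build is not given in the sources used here, and coordinates are those of the deposited annotation, on its own scaffold names. The deposited count table holds whole-number counts per locus for 75264 loci. It was checked against the 44 deposited transcript files: for every library, each locus count equalled the sum over its transcripts of coverage times exonic length divided by a read length of 75, rounded up, in 100% of loci. The true read length is not given in the sources used here. If it was not 75, all counts are off by a common factor, which leaves fold changes as they are but changes the apparent depth. Each transcript file matched the column of its own library best in 44 of 44 cases.

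Of the 75264 loci, 25572 carried a reference gene name and 49692 were unnamed loci assembled by StringTie, which held 7.08% of all counts. Gene symbols were available for 15952 loci, after 5344 LOC identifiers were given a symbol through the GeneIDs of the RefSeq gene table of assembly NCSU_Asbu1, from which no coordinates were used. A further 9620 loci had a LOC identifier alone. The assembly joined several reference genes in 301 loci, whose reads cannot be assigned to 1 of the genes, and such loci are named by all their genes. Reads shared between near-identical copies may be split in ways the counts do not show.

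Samples were grouped by the labels into 4 time points and 2 stocks, giving 8 groups of 4 to 6 fish. Fish numbers are unique in the labels, so no fish pair across groups. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 8 groups left 41529 loci, normalization was by TMM (factors 0.914 to 1.09), and a quasi-likelihood fit with 1 mean per group was tested by F tests with Benjamini-Hochberg adjustment over the loci tested, at a threshold of 0.05. The 44 libraries shared the estimate of spread (common dispersion 0.414). Contrasts compared adjacent time points, both released time points with both brooding time points, wild stock with lab stock over all and at each time point, and the interactions of stock with time and with release. Time contrasts weighted both stocks equally. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are given as CPM on TMM-adjusted library sizes, computed here from the deposited counts, with SD between fish. Principal components were computed on log2 CPM with a prior count of 2.

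The groups, the tests, the gene lists, the alternatives and the rule for genes to be named were fixed before the data were examined. The rule took, per main contrast and among loci past the threshold with a symbol and a mean of at least 1 CPM in some group, the 10 smallest p among the higher and the 10 among the lower, up to 4 members past the threshold per fixed list, and a set of neuropeptide, pituitary and immediate early genes for released against brooding whatever their p. For the tests over several contrasts and for the stock comparison at each time point it took the 3 smallest p. The rule fixed for list members used symbols or product names, but only symbols were searched, which departs from it for every list. Of 25 lists fixed in advance, 2 matched no locus in this way and could not be tested. Their replacements, chosen by symbol, were defined after the files had been seen, and a list of fatty acid and triglyceride synthesis genes after results had been seen, which gave 26 tested lists and 156 tests over 6 contrasts. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 156 tests. Members past the threshold were also counted with adjustment over the list alone.

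The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of the real loci, with 200 of 41529 loci changed. The changed loci were drawn from those with a mean of at least 1 CPM, so recovery at lower levels was not simulated. For R02 against B14 the procedure recovered 0% of loci changed 1.25-fold, 30% at 1.5-fold, 58% at 2-fold and 96% at 4-fold, with 5 false loci among 97 calls. For wild against lab stock it recovered 12%, 48%, 80% and 98% at those fold sizes, with 9 false loci among 128 calls. The Benjamini-Hochberg cutoff depends on how many loci change. In the real data these contrasts called 14 and 11654 loci, so the simulated shares need not hold for them.

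Alternatives were edgeR with median-of-ratios size factors, DESeq2 1.42.0, limma-voom with sample quality weights, no filter and a stricter filter on low counts (1 CPM in at least 9 libraries), surrogate variables (sva 3.50.0), a pituitary marker covariate, an additive model, fits on the compared time points alone, leaving out libraries of low agreement or with 2 runs, leaving out each of the 44 libraries in turn, and list tests with an estimated correlation and with fry. Restricting the test to loci with a reference name and halving the counts were added after the data had been seen. Group labels were also permuted in 70 splits, the real split included. Depth per library was 35004638 to 97267584 counts. Figures were drawn with matplotlib 3.10.9.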

Results

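The brains of 44 females of the mouthbrooding cichlid *Astatotilapia burtoni* were sampled over the maternal cycle. In this species the female carries eggs and young in the mouth and feeds little while doing so. The 4 time points were 2 days (B02) and 14 days (B14) of mouthbrooding, and 2 days (R02) and 14 days (R14) after the fry had been released. Each time point held fish of a wild-derived stock (WS) and of a laboratory stock (LS). Group sizes were 4 WS and 5 LS fish at B02, 6 and 6 at B14, 6 and 5 at R02, and 6 and 6 at R14, so that 22 fish came from each stock. Libraries held 35004638 to 97267584 counts, and all but 1 held 55507935 or fewer. The deepest was lab fish 5 at B02. Correlations of log2 CPM between pairs of libraries ranged from 0.870 to 0.949.

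Stock was the main axis of difference between the brains. The first principal component held 18.8% of the variance, and stock accounted for 96.7% of its scores against 0.769% for time point. The second component held 6.18% of the variance, of which time point accounted for 11.3%. The median correlation of a library with its own group averaged 0.922 ± 0.00589 (SD, n = 22) in wild stock and 0.931 ± 0.00333 (SD, n = 22) in lab stock. A single library, wild fish 2 at R02, lay more than 3 scaled median absolute deviations below the median of all libraries in this measure. It did so barely, at 0.90921 against a cutoff of 0.90925 pooled over both stocks.

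**Figure D1:**
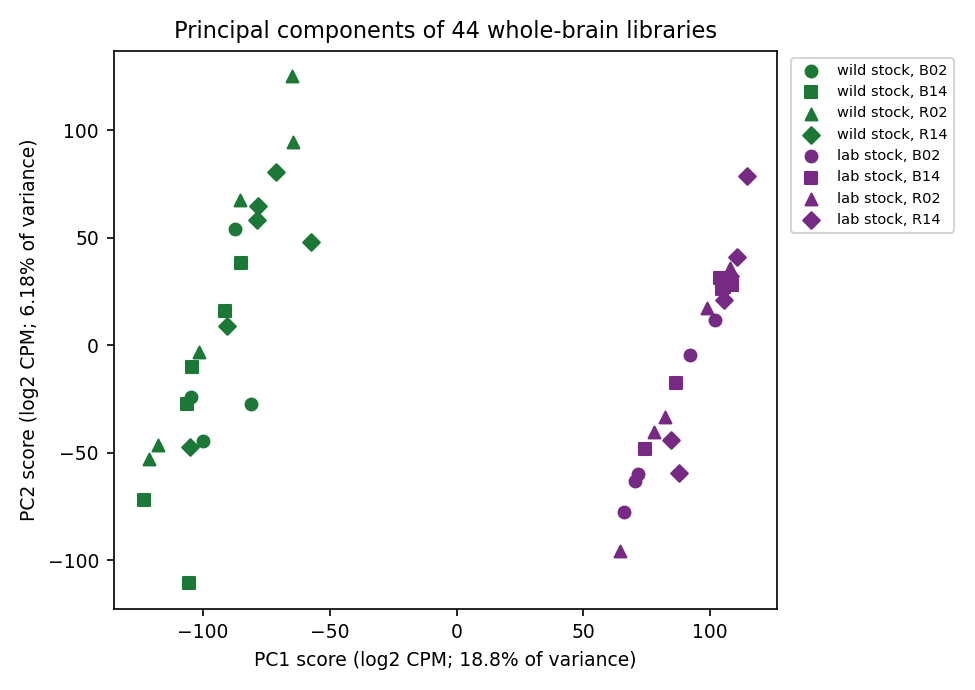
Scores of 44 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis. Colour marks the stock and marker shape the time point. On the first component the lab stock fish sit between 64.6 and 114 and the wild stock fish between -123 and -57.3.

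Across the 4 time points few loci changed, among them insig1 of sterol regulation and pdk2a, a kinase that inhibits pyruvate dehydrogenase. The test for any difference between time points called 8 of 41529 loci (edgeR quasi-likelihood, Benjamini-Hochberg), and 2675 had an unadjusted p under 0.05. The named loci with the smallest p were insig1, pdk2a and cwf19l1. Also called were klhl24, LOC102293328, LOC102301523 and the unnamed loci MSTRG.70392 and MSTRG.5007, which fall outside the naming rule or its first 3 and were chosen after their values were seen. Insig1 averaged 53.4 ± 12.4 CPM (SD, n = 9) at B02, 35.7 ± 5.76 (n = 12) at B14, 60.1 ± 8.94 (n = 11) at R02 and 54.8 ± 12.3 (n = 12) at R14. Cwf19l1 averaged 1.47 ± 1.82 CPM at R14 with fish from 0 to 4.70, 0.167 ± 0.537 at R02 with a highest fish of 1.79, 0.0182 ± 0.0397 at B02 and 0.00474 ± 0.0164 at B14. DESeq2 called 86 loci in the same test, and with surrogate variables 0 were called.

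Between late mouthbrooding (B14) and the second day after release (R02), a few genes of lipid synthesis and its control rose. Insig1, whose product restrains the processing of the sterol-regulated SREBP factors and which is itself their target, increased 1.70-fold (log2 0.76 ± 0.12 SE, edgeR adjusted p = 0.00634). Srebf1, which encodes an SREBP factor that drives lipid synthesis genes, rose 1.46-fold. Fasn, the fatty acid synthase, rose 1.48-fold, and acsl3b, a long-chain acyl-CoA synthetase, rose 1.28-fold. Pdk2a fell by 1.47-fold (log2 -0.56 ± 0.10 SE, edgeR adjusted p = 0.0152).

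In full, 14 loci changed between R02 (n = 11) and B14 (n = 12), 6 higher and 8 lower, while 2615 had an unadjusted p under 0.05. Fasn stood at 185 ± 34.6 CPM (SD) at R02 and 126 ± 23.96 at B14, srebf1 at 109 ± 21.7 and 74.9 ± 8.53, and acsl3b at 102 ± 12.9 and 80.3 ± 9.93. Also higher were odc1, the rate-limiting enzyme of polyamine synthesis (log2 0.55 ± 0.11 SE), and wee1, a kinase that restrains entry into mitosis (0.69 ± 0.14). The lower loci were klhl24, an adaptor of ubiquitin ligases (log2 -0.55 ± 0.09 SE, edgeR adjusted p = 0.00653), tefb, a clock-controlled transcription factor (-1.39 ± 0.28), slc27a6 of the fatty acid transport protein family (-0.66 ± 0.13), rin2 (-0.71 ± 0.14), fam169b (-0.77 ± 0.15), si:ch211-106h11.3 (-0.85 ± 0.17), pdk2a and the unnamed locus MSTRG.70392. Tefb fell from 52.8 ± 15.4 CPM at B14 to 19.9 ± 8.80 at R02. Except for insig1, klhl24 and pdk2a, the genes with a symbol had an edgeR adjusted p = 0.0456. All 11 R02 fish lay beyond the B14 mean in the direction of the change for insig1, srebf1, fasn, acsl3b, odc1, pdk2a and tefb, and 10 of 11 did for klhl24 and wee1. Insig1 lies on scaffold NW_005179401.1 from 6512389 to 6519487, fasn on NW_005180019.1 from 270018 to 295018, srebf1 on NW_005179470.1 from 1269194 to 1284967 and pdk2a on NW_005179405.1 from 3207162 to 3216576. Of 44 fits that each left out 1 library, insig1 and klhl24 stayed past the threshold in all 44, pdk2a in 42, srebf1 in 21, wee1 in 18, rin2 in 16, fasn, odc1 and si:ch211-106h11.3 in 14 each, fam169b and slc27a6 in 9 each, tefb in 8 and acsl3b in 7. Of 13 alternatives insig1 passed in 13, klhl24 in 11, pdk2a in 10, srebf1 in 9 and the other genes with a symbol in 6 to 8. MSTRG.70392 stayed past the threshold in all 44 fits but in 7 of 12 alternatives. In lab stock it stood at 32.9 ± 8.28 CPM at B14 and 29.1 ± 8.60 at R02. Among wild fish only 3, all at B14, exceeded 0.126 CPM. DESeq2 called 106 loci, and 2 were called when the libraries with 2 runs (lab fish 12 at B14, wild fish 48 at R02) were left out.

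**Figure D2:**
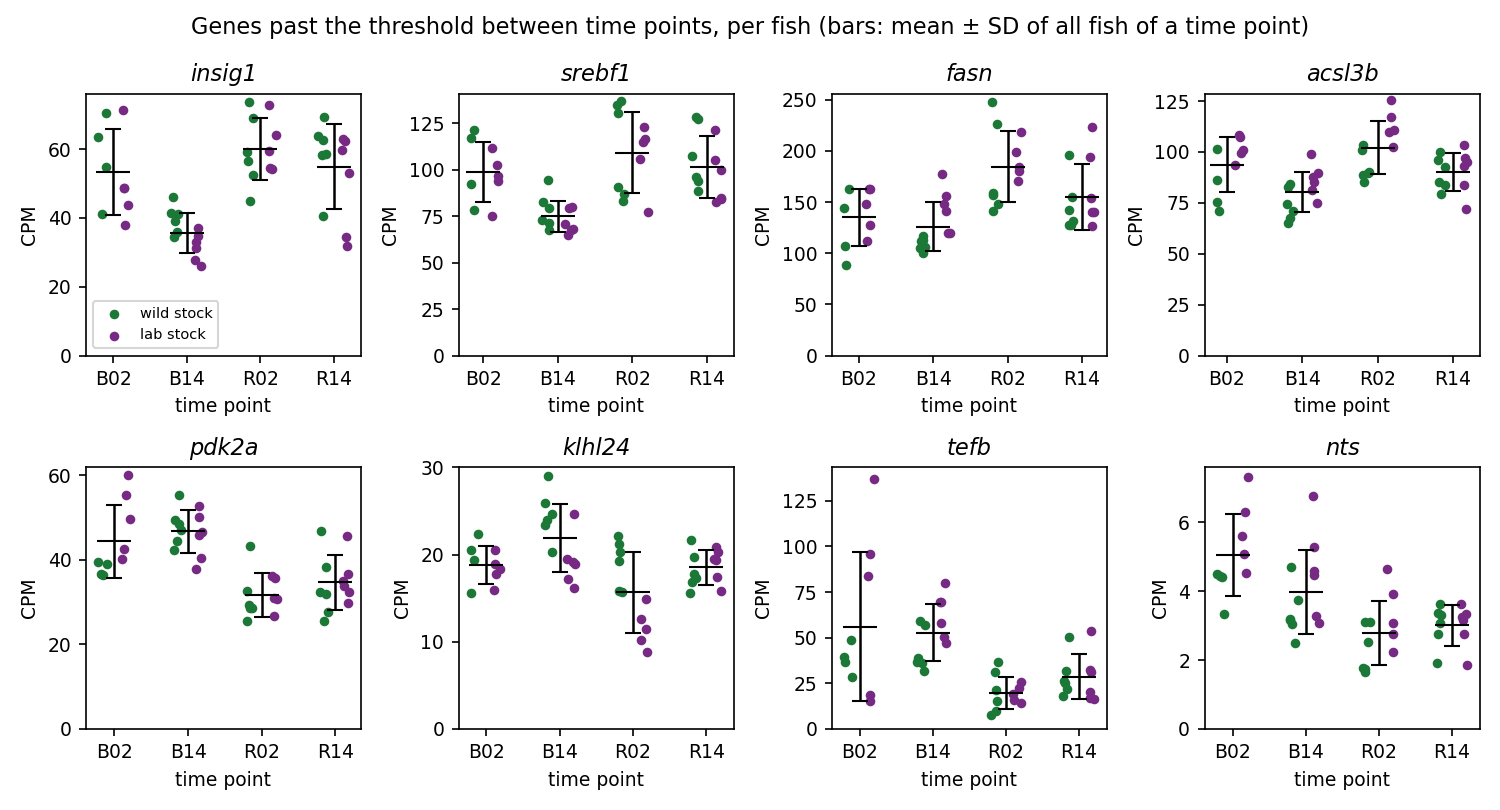
Levels of 8 genes in CPM (y axis) for each fish by time point (x axis), coloured by stock, with the mean and SD over all fish of a time point in black. Insig1 averages 35.7 CPM at B14 and 60.1 at R02, and pdk2a averages 46.8 and 31.7.

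The fasting and sterol lists moved between R02 and B14 by camera with the preset correlation, but not with an estimated one. With fry in either direction the fasting list passed (adjusted p = 0.00961), and in one direction no list did. Fry asks whether members differ at all, not whether they differ more than other genes, so a few strong members can give a pass. Of 28 genes on the list of glucocorticoid and fasting responsive genes, pdk2a alone was lower over all loci, and 5 were lower when adjusted over the list alone: pdk2a, pdk4, cebpd, fbxo32 and mt2. Pdk4, a second kinase of that family, stood at 33.5 ± 7.55 CPM at R02 and 45.8 ± 8.87 at B14. The list moved down by camera (adjusted p = 3.06e-05), but adjusted p = 0.285 with an estimated correlation. Among 22 sterol synthesis and uptake genes insig1 alone was higher, over all loci and over the list alone, while 21 had a positive log2 change. That list moved up (camera adjusted p = 3.06e-05), with adjusted p = 0.285 with an estimated correlation. A list of fatty acid and triglyceride synthesis was defined after these results had been seen and holds genes called here, so its tests between time points are not used.

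The lists of cell proliferation, microglia and heat shock genes also moved between R02 and B14 by camera with the preset correlation, but not with an estimated one or by fry. None of 30 cell proliferation genes passed over all loci, and mcm5 (log2 0.83 ± 0.24 SE) and mcm4 (0.47 ± 0.15), helicase subunits of DNA replication, were higher when adjusted over the list alone. The list had 26 positive members (camera adjusted p = 2.81e-07, and adjusted p = 0.549 with an estimated correlation). All 17 microglia and immune cell genes had negative values and 0 passed, over all loci or over the list alone (camera adjusted p = 0.000542, and adjusted p = 0.831 with an estimated correlation). Their spread between fish was wide, as for mpx, a neutrophil peroxidase, with 16.1 ± 34.3 CPM at B14. The heat shock and unfolded protein response list moved up with 0 of 29 members past the threshold (camera adjusted p = 0.000470, and adjusted p = 0.549 with an estimated correlation). Members of other lists passed when adjusted over their own list alone. Nes, the radial glia filament nestin, was higher (log2 0.54 ± 0.13 SE) among 16 radial glia and astroglia genes. The growth hormone receptor genes ghra and ghrb were lower (-0.36 ± 0.11 and -0.51 ± 0.15) among 19 insulin, growth hormone and IGF genes. Cry1b was lower (-0.40 ± 0.13) among 26 clock genes.

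Between early and late mouthbrooding, from B02 (n = 9) to B14 (n = 12), no locus passed the threshold. The count was 0 by edgeR quasi-likelihood test and 0 by limma-voom, 1916 loci had an unadjusted p under 0.05, and DESeq2 called 49 (34 higher, 15 lower). Insig1, srebf1, fasn and acsl3b had lower means at B14 than at B02, whereas slc27a6 had a higher one (7.16 ± 1.23 against 5.24 ± 1.63 CPM). Insig1 averaged 53.4 ± 12.4 CPM at B02 and 35.7 ± 5.76 at B14 (log2 -0.60 ± 0.13 SE, edgeR adjusted p = 0.274). Srebf1 averaged 98.8 ± 16.1 and 74.9 ± 8.53 (log2 -0.40 ± 0.11 SE, edgeR adjusted p = 0.713). In lab stock fasn hardly differed, at 142.7 ± 22.4 CPM at B02 and 143.6 ± 22.2 at B14. When adjusted over the list alone, insig1 was lower among the sterol genes and rbp3 among 24 retina and pineal genes, and cebpd was higher among the fasting genes (17.1 ± 6.68 CPM at B02, 38.2 ± 28.98 at B14).

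By camera, the fasting list moved up (adjusted p = 0.0304) and the sterol list (adjusted p = 0.00273), the heat shock list (adjusted p = 0.00976), the choroid plexus, ependyma and meninges list (adjusted p = 0.00480), the proliferation list (adjusted p = 0.0254) and the oxidative phosphorylation list (adjusted p = 0.0144) moved down. The lowest adjusted p = 0.549 with an estimated correlation, among these lists. The B14 fish enter both this contrast and that of R02 against B14, so opposite signs in them arise in part from the shared fish. Leaving out wild fish 28 at B02 gave 3 loci, and leaving out wild fish 6, 16 or 21 at B14 gave 1.

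In the later interval after release, from R02 (n = 11) to R14 (n = 12), 3 loci changed, 2 higher and 1 lower, and none had a gene symbol. They were named after their values were seen. LOC102293328, on locus MSTRG.44362, averaged 23.9 ± 13.1 CPM at R02 and 228 ± 146 at R14 (log2 3.19 ± 0.49 SE, edgeR adjusted p = 0.00302), after 150.5 ± 106 at B02 and 46.7 ± 36.97 at B14. LOC102301523 followed the same order, with 18.5 ± 6.08, 14.5 ± 3.65, 11.4 ± 2.54 and 26.6 ± 10.5 CPM at B02, B14, R02 and R14 (log2 1.2 ± 0.19 SE for R14 against R02, edgeR adjusted p = 0.00302). The unnamed locus MSTRG.5007 was lower at R14 (0.156 ± 0.173 against 0.440 ± 0.391 CPM, edgeR adjusted p = 0.0266). No fitted fold is given for it, since all 6 wild fish at R14 were at 0, while lab fish stood at 0.312 ± 0.0880 at R14 and 0.5965 ± 0.281 at R02. An unadjusted p under 0.05 was seen for 1699 loci, and DESeq2 called 65. LOC102293328 was not past the threshold with limma-voom or with surrogate variables, and LOC102301523 was not with only the libraries of the compared time points. Both kept their calls in all 44 fits that left out 1 library, whereas MSTRG.5007 did in 31 of 44, and in 4 of 11 alternatives.

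Of 11 blood genes, 2 were higher at R14 than at R02 over the list alone: alas2, the first enzyme of haem synthesis in red cells (25.1 ± 13.6 CPM against 11.9 ± 3.27), and klf1, an erythroid transcription factor (log2 0.82 ± 0.30 SE). None of the 11 passed over all loci. The blood list moved up (camera adjusted p = 0.00221, and adjusted p = 0.285 with an estimated correlation), as did that of 20 oligodendrocyte and myelin genes (camera adjusted p = 0.0190, and adjusted p = 0.549 with an estimated correlation), none of which passed. The lists of heat shock genes (camera adjusted p = 0.00221) and of oxidative phosphorylation (camera adjusted p = 0.000672) moved down, with an adjusted p = 0.549 at the lowest with an estimated correlation.

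Taking both time points after release (n = 23) against both during mouthbrooding (n = 21), 3 genes fell and none rose. Pdk2a was lower, at 33.2 ± 5.94 CPM (SD) against 45.8 ± 6.71 (log2 -0.44 ± 0.07 SE, edgeR adjusted p = 0.0110), in 22 of 23 released fish relative to the brooding mean. Tefb stood at 24.4 ± 11.5 against 54.2 ± 28.4 CPM (log2 -1.12 ± 0.20 SE, edgeR adjusted p = 0.0381), lower in 23 of 23. Nts, the precursor of the neuropeptide neurotensin, stood at 2.90 ± 0.765 against 4.45 ± 1.298 CPM (log2 -0.61 ± 0.11 SE, edgeR adjusted p = 0.0385), lower in 22 of 23. Nts lies on NW_005179589.1 from 1067051 to 1072179 and tefb on NW_005179920.1 from 31783 to 39330. An unadjusted p under 0.05 was seen for 3795 loci, and DESeq2 called 115 (50 higher, 65 lower). Pdk2a kept its call in all 44 leave-one-out fits, nts in 15 and tefb in 19. Of 12 alternatives pdk2a passed in 11, failing with surrogate variables, tefb in 9 and nts in 8. The count was 10 (5 higher, 5 lower) when the test was restricted to loci with a reference name and 0 with surrogate variables. It was 1 with the pituitary covariate and 1 without the library of low agreement.

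Of 28 fasting genes, 6 were lower after release when adjusted over the list alone (pdk2a, fbxo32, mt2, pdk4, angptl4 and cpt1b) and irs2b, an adaptor of the insulin receptor, was higher (log2 0.38 ± 0.12 SE), while pdk2a alone passed over all loci. The list moved down by camera with the preset correlation, but not with an estimated one (camera adjusted p = 0.00314, and adjusted p = 0.549 with an estimated correlation). With fry in either direction, which does not compare members with other genes, the list passed (adjusted p = 0.00115). Fbxo32, a ubiquitin ligase of muscle wasting, stood at 2.60 ± 0.942 against 4.65 ± 2.92 CPM, and mt2, a metallothionein, at 145 ± 43.6 against 206 ± 61.0. Of 30 proliferation genes, tpx2, mcm4, cenpe, mki67 and ccna2 were higher over the list alone and 0 over all loci, with mki67, the antigen of cycling cells, at 14.5 ± 5.81 against 9.99 ± 5.23 CPM (camera adjusted p = 3.06e-05, and adjusted p = 0.706 with an estimated correlation). Of 17 microglia and immune genes, mpx, csf1r, cd8a, spi1 and c1qb were lower over the list alone and 0 over all loci, with csf1r, the receptor that macrophages and microglia need, at 18.4 ± 7.09 against 24.3 ± 9.30 CPM (camera adjusted p = 1.98e-05, and adjusted p = 0.677 with an estimated correlation). The lists of interferon response (camera adjusted p = 0.0163), circadian clock (0.0254), ribosomal proteins (0.00221) and oxidative phosphorylation (0.0254) also moved down, none with an adjusted p below 0.549 with an estimated correlation.

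Genes of appetite, parental care and neural activity that had been named in advance did not pass between released and brooding females. Npy, which promotes feeding, differed by log2 0.25 ± 0.28 (SE, edgeR adjusted p = 0.869), and agrp, also a feeding signal, by 0.23 ± 0.39. Avp, which encodes vasotocin, differed by log2 -0.42 ± 0.32 and gal, the galanin precursor, by -0.43 ± 0.21 (edgeR adjusted p = 0.536). Values for gnrh1, gnrh3, fosab, fosb, egr1 and the joined locus of fosaa and mlh3 lay between log2 -0.33 and 0.49, with fosb the highest (0.49 ± 0.19 SE, edgeR adjusted p = 0.451). Cart, oxt and cyp19a1b were not matched to a locus by symbol and were not analysed here. The pituitary hormone genes prl, pomc and gh1 differed by log2 0.66 ± 1.08, 0.68 ± 1.03 and 0.52 ± 1.14, each with the opposite sign when wild fish 47 at R02 was left out (-1.21, -1.02 and -1.60). Their levels varied widely between fish, with prl at 136 ± 154 CPM after release and 86.1 ± 146 during brooding, and pituitary markers averaged log2 CPM 4.66 ± 1.58 (SD, n = 5) in lab fish and 0.820 ± 2.18 (n = 6) in wild fish at R02.

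The brains of the stocks differed at 11654 of 41529 loci, 28.1% of those tested, with 5533 higher and 6121 lower in wild stock. Lmo7, a LIM domain protein of cell junctions, stood at 45.02 ± 5.32 CPM (SD, n = 22) in wild stock and 19.3 ± 2.84 (n = 22) in lab stock (log2 1.199 ± 0.06 SE, edgeR adjusted p = 1.28e-18). Mrs2, a mitochondrial magnesium channel, stood at 19.7 ± 2.97 and 8.57 ± 1.21 CPM (log2 1.21 ± 0.07 SE). Rrm2, a subunit of ribonucleotide reductase, was lower in wild stock, at 8.90 ± 2.38 against 36.6 ± 6.17 CPM (log2 -2.02 ± 0.11 SE, edgeR adjusted p = 5.04e-18). Tcf25 stood at 30.9 ± 3.84 against 88.1 ± 20.7 CPM (log2 -1.51 ± 0.09 SE). For these 4 genes every wild fish lay on the same side of every lab fish.

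Other genes with a symbol among the 10 smallest p in each direction were higher in wild stock by log2 1.15 to 3.56 (lca5l, cunh12orf56, myh7b, lsm2, ccdc125, opn7b, si:dkeyp-72e1.6 and cetn4) or lower by log2 -0.61 to -4.28 (myof, ccdc89, dtd1, oclna, nprl3, pnpla7, slc7a6 and the joined locus of trim33l and zgc:171704). Lca5l showed the largest of the higher values (3.56 ± 0.26 SE) and ccdc89 the largest of the lower ones (-4.28 ± 0.34), at 1.00 ± 1.41 against 18.6 ± 10.995 CPM. Lmo7 lies on NW_005179580.1 from 856579 to 906611, mrs2 on NW_005179577.1 from 344658 to 356509, rrm2 on NW_005179630.1 from 831052 to 841305 and tcf25 on NW_005179409.1 from 3924441 to 3945959. The share called was 20.9% among 15053 loci with a symbol (3140 loci, 1654 higher and 1486 lower), 27.9% among 7044 with a LOC identifier and 33.7% among 19432 unnamed loci. Called loci with a symbol had a median absolute log2 change of 0.43, and unnamed ones 1.93. When surrogate variables were added, 21 loci were called. Stock itself was given to 98.3% by these variables.

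**Figure D3:**
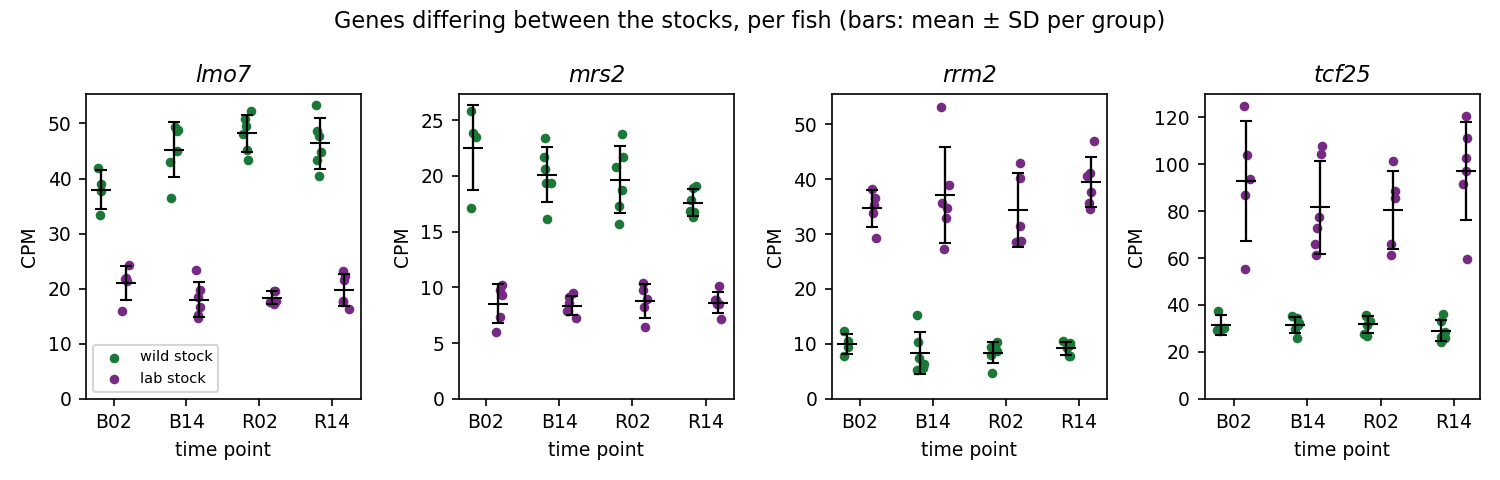
Levels of lmo7, mrs2, rrm2 and tcf25 in CPM (y axis) for each fish by time point (x axis), coloured by stock, with mean and SD per group in black. Over all time points lmo7 averages 45.02 CPM in wild and 19.3 in lab stock, and rrm2 averages 8.90 and 36.6.

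Immune and cell cycle genes were among those that differed between the stocks. Of 14 interferon response genes 1 was higher and 6 were lower in wild stock (1 and 7 when adjusted over the list alone). The antiviral gene rsad2 (log2 -2.02 ± 0.27 SE) and its neighbour cmpk2 (-1.10 ± 0.20) were lower, as were irf7, a regulator of interferon genes (-0.68 ± 0.15), and dhx58, a sensor of viral RNA (-0.48 ± 0.10). Of 30 proliferation genes 8 were higher and 3 lower (9 and 3 over the list alone). Lower were rrm2, the checkpoint kinase gene bub1b (-1.25 ± 0.11) and the joined locus of kif11 and LOC102295087 (-1.03 ± 0.21), whereas cdk1 (0.64 ± 0.16) and ccnb3 (0.71 ± 0.18), which drive mitosis, were higher. Csf1r, a microglial receptor, was higher (log2 0.70 ± 0.15 SE) and was the only one of 17 microglia and immune genes called. None of these lists passed for a shift in one direction, with camera adjusted p = 0.116, 0.459 and 0.716 for interferon, proliferation and microglia. With fry in either direction, which allows members to go both ways, 12 of 26 lists passed for stock. Among them were interferon (adjusted p = 0.00678) and proliferation (5.90e-27), but not microglia. Fry asks only whether members differ, and 20.9% of all loci with a symbol were called, so a pass does not set a list apart.

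Some glial, neuronal and endocrine genes differed as well, but no such list passed by camera, and of those below only the immediate early genes did with fry in either direction (adjusted p = 0.0104). The shares called among radial glia, neuron class, monoamine, appetite and immediate early genes lay below the 20.9% among all loci with a symbol. Fabp7a, a fatty acid binding protein of radial glia, was higher in wild stock (log2 1.14 ± 0.22 SE), as was the glutamate transporter gene slc1a3 (0.32 ± 0.08), and glula, glutamine synthetase, was lower (-0.68 ± 0.23), of 16 radial glia and astroglia genes. Of 27 neuron class genes 3 were higher, among them the vesicular glutamate transporter genes slc17a8 (0.55 ± 0.17) and slc17a6b (0.16 ± 0.06). Of 24 monoamine genes the receptor genes htr1a, drd3 and drd2 were higher (log2 0.16 to 0.31) and maob was lower (-0.60 ± 0.18). Of 25 appetite genes lepr, the leptin receptor, was higher (0.49 ± 0.11), and galr1a (-0.45 ± 0.14) and mc4r (-0.29 ± 0.10) were lower. Gnrh1, which encodes the releasing hormone of gonadotropins, was lower at 0.805 ± 0.449 against 1.48 ± 0.755 CPM, and of the growth hormone receptor genes ghra was lower (-0.44 ± 0.08) and ghrb higher (0.37 ± 0.11). Of 27 immediate early genes 2 were higher, klf6a and the joined locus of fosaa and mlh3, and 3 were lower, among them egr2 and dusp5. Glula, slc17a6b, drd2, mc4r and gnrh1 lost their call in at least 1 fit that left out 1 library.

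Some metabolic genes differed by stock. Among all loci with a symbol 20.9% were called. The shares called among sterol, glycolysis and hypoxia, heat shock, fasting, clock and oligodendrocyte genes lay below that. Those among ribosomal protein, oxidative phosphorylation, fatty acid and thyroid axis genes lay above it. All 4 sterol genes that passed, of 22, were lower in wild stock: fdft1, squalene synthase (log2 -0.68 ± 0.09 SE), sqle (-0.49 ± 0.17), nsdhl and the low-level ldlr. Of 39 glycolysis and hypoxia genes 3 were higher, among them hk2 (0.36 ± 0.11), and 4 lower, among them aldoc at 1365 ± 312 against 1771 ± 265 CPM. Of 29 heat shock genes 3 were higher, led by hspa1b (2.00 ± 0.34), and 2 were lower. Ribosomal protein genes moved up in wild stock, with 15 higher and 2 lower of 78 (camera adjusted p = 0.00273, and adjusted p = 0.940 with an estimated correlation). Oxidative phosphorylation genes did so too, with 13 higher and 2 lower of 54 (camera adjusted p = 0.0304, and adjusted p = 0.966 with an estimated correlation). Both of these lists were defined after the files had been seen. Of the fatty acid list, defined after results had been seen, 5 were higher and 6 lower of 47. Of 28 fasting genes cpt1b was higher and foxo3a lower, of 26 clock genes cry1b alone was higher, of 14 thyroid axis genes tg was higher and dio1 and tshr lower, and none of 20 oligodendrocyte genes passed. Sqle, foxo3a, tg and tshr lost their call in at least 1 fit that left out 1 library.

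Markers of tissue outside the neural parenchyma moved both ways between the stocks. The shares called among epithelium, pituitary, blood and muscle, cartilage and bone genes lay below the 20.9% among all loci with a symbol. Those of the retina and choroid plexus lists lay above it. Of 24 retina and pineal genes 7 were higher and 3 lower, and 2 of the higher, rhob and rhoab, encode small GTPases that were matched by name alone. Rlbp1, a retinoid carrier, was lower (log2 -1.03 ± 0.14 SE), and rcvrn, recoverin, was higher (1.32 ± 0.37) at under 1 CPM. Of 24 choroid plexus, ependyma and meninges genes 2 were higher, led by rsph4a of motile cilia (1.12 ± 0.11), and 4 were lower, led by kl (-1.42 ± 0.22). Of 12 skin and mouth epithelium genes evplb alone was called (-3.13 ± 0.31), of 16 pituitary genes tbx19 alone (-0.65 ± 0.18) and of 11 blood genes nt5c2l1 alone (-0.83 ± 0.28). Of 29 muscle, cartilage and bone genes 2 were higher, mb and matn4, and 2 lower, neb and matn1. Nt5c2l1, matn4 and matn1 lost their call in at least 1 fit that left out 1 library.

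The stocks differed at every time point. Wild against lab stock gave 1468 loci at B02 (785 higher, 683 lower), 5022 at B14 (2281 and 2741), 2353 at R02 (1098 and 1255) and 2550 at R14 (1114 and 1436). Group sizes also differed at B02 and R02, but B14 and R14 both held 6 fish of each stock. The named genes with the smallest p were mrs2, lca5l and tcf25 at B02, lmo7, rrm2 and mrs2 at B14 and at R02, and lmo7, rrm2 and tcf25 at R14. Rrm2 differed by log2 -2.15 ± 0.20 (SE) at B14, -2.03 ± 0.21 at R02 and -2.10 ± 0.20 at R14, and lmo7 by 1.33 ± 0.12, 1.39 ± 0.12 and 1.23 ± 0.12. At B02 lmo7 stood at 37.99 ± 3.62 against 21.07 ± 3.07 CPM (SD) and rrm2 at 9.996 ± 1.87 against 34.7 ± 3.40. Of 6708 loci called at any time point 768 were called at all 4, each in the same direction. Independent lists would give 0.618, but these lists come from 1 fit with a shared estimate of spread. They are not independent, so part of the excess arises from that. The log2 change had the same sign at all 4 time points for 5653 of the 6708 (84.3%).

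Few loci passed a test for a stock difference that changed with time, which does not show that the other differences were stable, as interactions were not simulated. For the interaction of stock and time 1 locus passed, the unnamed MSTRG.70392 (edgeR adjusted p = 0.0291), which was named after its values were seen, and 2097 loci had an unadjusted p under 0.05. It lies on scaffold NW_005181190.1 from 19228 to 22393. In lab stock it ranged from 17.1 to 19.99 CPM in 6 fish and from 30.2 to 38.8 in 16, and in wild stock from 14.96 to 17.3 CPM in 3 fish, all at B14 (fish 15, 20 and 29), and from 0 to 0.126 in the other 19. No wild fish at another time point exceeded 0.126 CPM. The call was lost when any 1 of 9 B14 fish was left out (lab fish 7, 12, 18, 19, 22 and 41, wild fish 15, 20 and 29), and without the libraries of 2 runs. For the interaction of stock and release 0 loci passed by edgeR quasi-likelihood test and 0 by limma-voom, 2259 had an unadjusted p under 0.05, and DESeq2 called 37. DESeq2 called 33 loci for stock and time and limma-voom 0.

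**Figure D4:**
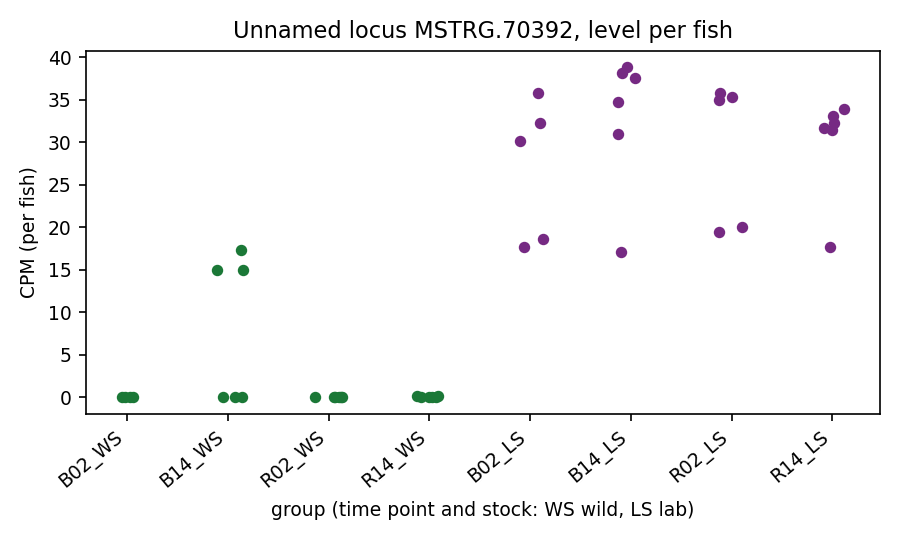
Level of the unnamed locus MSTRG.70392 in CPM (y axis) for each fish in the 8 groups (x axis). Of the wild stock fish, 3 at B14 sit between 14.96 and 17.3 CPM and 19 at 0.126 or below, and lab stock fish sit between 17.1 and 38.8.

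In the interaction of stock and release no list passed with an estimated correlation. The muscle, cartilage and bone list had 6 of 29 members higher over the list alone, with 0 over all loci, among them acta1b (log2 5.48 ± 1.69 SE) and ckm (5.51 ± 1.71), and it did not pass by camera (adjusted p = 0.152). Single fish stood out in the mean log2 CPM of this list, with 3.39 in wild fish 23 at R14, 3.05 in lab fish 5 at B02, 2.32 in lab fish 40 at R02 and 2.27 in lab fish 7 at B14, against 1.13 or less in every other fish. Microglia and immune genes (camera adjusted p = 0.000672), pituitary genes (0.0135) and ribosomal protein genes (0.000470) moved down with the preset correlation, with adjusted p = 0.831, 0.936 and 0.940 with an estimated correlation. None of their members passed. Over all 156 list tests, 30 passed by camera with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p = 0.285. With fry 0 passed in one direction and 16 in either direction, of which 0 were for this interaction, and the fatty acid list gave 3 of the 30 and 3 of the 16.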

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

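Chosen only after the result was seen were the tests of loci missing from 1 stock, of time of day, of a wrong label and of mixed ancestry, and thinning replaced a comparison of total counts already seen (42560133 ± 4989790 in wild and 45000955 ± 12759174 in lab stock, SD, n = 22 each, two-sided permutation p = 0.511).

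The stocks differed at 11654 loci. Permuted stock labels gave at most 4 loci in the other splits, with 1 of 70 splits as large (the real one), so chance can be excluded, as at B02 (1468, highest other 1, 1 of 70), B14 (5022, highest other 235, 1 of 70), R02 (2353, highest other 1, 1 of 70) and R14 (2550, highest other 0, 1 of 70). Depth as the whole cause is argued against, since 94.1% of the called loci were called in the same direction after every library was thinned to 35004638 counts. Near-absence of loci from 1 stock as the whole cause is argued against too. Over all called loci, 12.3% had a lower stock under 10% of the higher one. The share was 0.764% among those with a symbol, the class set for this test, 10.2% with a LOC identifier alone and 18.4% among unnamed loci. Partial loss of reads in 1 stock would give smaller folds and was not tested. Called neighbours on a scaffold shared their direction in 63.7% of 3260 pairs, above all 1000 shuffles (46.8% to 52.4%). Variants or copy number shared by neighbouring loci may give this for part of the pattern. Overlapping loci that may share reads were not left out, however, so the test cannot tell these apart. The 417 pairs with symbols on both sides gave 53.5%, inside their shuffles (43.4% to 58.8%). Inherited differences and the rearing history of the stocks stay open and were not tested.

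From B14 to R02, insig1, srebf1, fasn and acsl3b rose and pdk2a fell. Permuted time labels gave at most 5 loci against 14, with 1 of 70 splits as large. By this share, which was not adjusted for the number of counts compared, chance is argued against. The count itself is less firm: 33 of 44 fits that left out 1 library moved it by over 1.5 times, with a lowest of 3, and it was 2 to 4 under 5 alternatives, within the highest other split. Pituitary tissue in the libraries as the cause is argued against: with a pituitary covariate the median ratio of the log2 change to that without it was 0.991 over 13 named loci (0.952 to 1.02), while 6 pituitary hormone genes shifted by a median of 0.35, yet only 3 of the 13 stayed past the threshold, most of the others having started at an adjusted p = 0.0456 (edgeR). Time of day cannot be told apart from the sampling stage, since 1 of 25 other clock genes (cry1b) passed beside tefb when adjusted over the list alone and the labels give no hour. A return to feeding after release may underlie the pattern, as a hypothesis that no feeding record here tests.

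The unnamed locus MSTRG.70392 stood in steps and was marked by its interaction of stock and time (edgeR adjusted p = 0.0291), a call lost when any 1 of 9 B14 fish was left out (lab 7, 12, 18, 19, 22 and 41, wild 15, 20 and 29) or without the libraries of 2 runs (0 loci each). Permuted labels gave as many loci in 13 of 70 splits, with up to 1065 against the real 1, so chance cannot be excluded. A count that high may point to a structure of the samples, which was not tested. A wrong stock label is argued against, as 0 of the 3 wild fish lay among the lab fish on the first principal component, and parents of both stocks are too, as 3 of 3 lay among the other wild fish (-123 to -57.3). A smaller inherited segment stays open. A presence or copy variant may give such steps. One spanning more than this locus remains undecided, with a highest r = 0.569 over 22 wild fish to another locus of the scaffold. That locus was the low-level LOC102288683, with a mean of 0.00493 CPM in wild stock. A variant of MSTRG.70392 alone need not move its neighbours, so this correlation cannot test it.

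Other counts were also set against 70 splits. Any difference between time points (8 loci) was reached in 4 of 70 splits, with up to 41, so chance cannot be excluded. The count for R14 against R02 (3) was reached in 1 of 70, with a highest other of 2. That for released against brooding (3) was reached in 2 of 70, with a highest other of 3. These shares were not adjusted for the number of counts compared and the counts are small, so chance is not excluded for either. For R14 against R02 the count fell to 1 with limma-voom or surrogate variables and was 2 at the lowest with 1 library left out, within the highest other split. For released against brooding another split gave the same count, and 24 of 44 fits that left out 1 library gave 1. The counts of 0 for B14 against B02 and for stock and release were reached in 70 of 70, with highest others of 3 and 4.

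Of 64 sets of values examined, 8 held a fish far from the rest. The rule used gives about 1 in 20 by chance for normally distributed values only. Many of the sets also hold the same fish, so no excess over chance can be read from this count. Total counts stood apart in lab fish 5 at B02 (97267584) and lab fish 43 at R02 (55507935). At B02 the fish apart were lab fish 13 for cwf19l1 (0.115 CPM), wild fish 28 for wee1 (7.11 CPM), lab fish 5 for avp (154.6 CPM) and LOC102301523 (32.3 CPM), and lab fish 45 for egr1 (407 CPM), and among wild fish at B02 it was fish 28 for tcf25 (37.6 CPM). The change with release differed between the stocks for the lists of microglia and immune genes (camera adjusted p = 0.000672), pituitary genes (0.0135) and ribosomal proteins (0.000470), none with an estimated correlation (lowest adjusted p = 0.831).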

How the results depend on the processing

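The fits restricted to loci with a reference name and those on halved counts were chosen after seeing the data. No paired analysis was possible because fish numbers are unique. Median-of-ratios size factors and halved counts moved no count by over 1.5 times. DESeq2 called 86 loci for any time difference, 49 for B14 against B02, 106 for R02 against B14, 65 for R14 against R02, 115 for released against brooding, 2496 for stock at B02, 33 for stock by time and 37 for stock by release. Limma-voom gave 1 for R14 against R02, 8 for released against brooding, 4217 for stock at R14 and 0 for stock by time. For R02 against B14 the count was 3 with no filter, 3 with the additive model, 4 with the pituitary covariate, 7 without the library of low agreement (wild fish 2 at R02), 2 without the libraries of 2 runs and 2 with only the compared time points. The additive model gave 5 for any time difference and 5 for released against brooding, which fell to 1 with the pituitary covariate and 1 without the library of low agreement. Stock by time gave 2 with the stricter filter and 0 without the libraries of 2 runs. Only the compared time points gave 838 at B02 and 1117 at R02. Loci with a reference name gave 10 for released against brooding, 4965 for stock, 419, 2368, 625 and 807 at B02, B14, R02 and R14, where fewer loci were tested, and 0 for stock by time. List tests gave 0 with an estimated correlation and 0 with fry in one direction, and 16 of 156 with fry in either direction (12 for stock, 2 each for R02 against B14 and released against brooding, of which 1 each came from the fatty acid list chosen after results were seen). Where no reason is named, the cause was not tested.

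With 10 surrogate variables the counts were 0 for any time difference, 1 for R14 against R02, 0 for released against brooding, 21 for stock and 21, 14, 18 and 28 at B02, B14, R02 and R14. Together the variables gave 98.3% of the stock indicator, which accounts for the lost stock calls. Of 84 stock genes 25 reversed: ccdc125 -0.96, ccdc89 1.27, slc7a6 1.98, mc4r 0.22, maob 0.61, egr2 0.50, foxo3a 0.36, ghrb -0.41, igfbp3 0.93, fdft1 0.27, ldlr 2.25, nsdhl 1.48, p4ha2 -0.40, hk2 -1.21, cry1b -1.16, sdf2l1 -1.44, creld2 0.29, kif11;LOC102295087 1.54, slc1a3 -0.18, csf1r -2.40, tshr 0.60, rhob -0.67, guca1a -0.55, matn4 -1.42 and klb 0.78 (log2). For released against brooding, agrp (-0.36), gnrh1 (-0.067), pomc (-0.40) and egr1 (-0.36) reversed. The pituitary covariate reversed gnrh1 (-0.038), prl (-0.33), pomc (-0.27) and gh1 (-0.0052), and leaving out the libraries of 2 runs reversed egr1 (-0.010). None of these genes had passed between released and brooding fish.

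Leaving out each library in turn gave 0 to 3 loci for B14 against B02, 3 to 14 for R02 against B14, 1 to 4 for released against brooding, 0 to 3 for stock by time and 0 to 2 for stock by release. For released against brooding, prl ranged from -1.21 to 0.95, pomc from -1.02 to 1.71 and gh1 from -1.60 to 1.62 (log2; all 3 lowest without wild fish 47 at R02), and egr1 from -0.085 (without lab fish 39 at R14) to 0.44. Of the 84 stock genes 69 stayed past the threshold in all 44 fits, not mc4r, gnrh1, gnrh2, drd2, foxo3a, igfbp3, sqle, epas1, glula, slc17a6b, tg, tshr, nt5c2l1, matn4 and matn1. Insig1 stayed past it for R02 against B14 in 44 of 44 and in 13 of 13 alternatives. The count for R02 against B14 moved by over 1.5 times in 33 of 44 fits, except without lab fish 5 and 45 or wild fish 9 and 28 at B02, wild fish 31 at R02, or wild fish 23, 25 and 30 or lab fish 24, 36 and 39 at R14, and was lowest (3) without lab fish 40 at R02. That for released against brooding fell to 1 in 24 of 44. Stock by time gave 0 without any of 9 B14 fish (lab 7, 12, 18, 19, 22 and 41, wild 15, 20 and 29), 2 without wild fish 30 at R14, and 3 without wild fish 9 or 28 at B02 or lab fish 34 at R14. Stock by release gave 1 without wild fish 9 and 2 without wild fish 28 at B02. No count for any time difference (6 to 12), R14 against R02 (2 to 4) or stock (10991 to 12142) moved that far. Of the smallest simulated changes for R02 against B14, 0% were found.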

Other observations

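The list of fatty acid and triglyceride synthesis, the symbol lists of ribosomal proteins and oxidative phosphorylation, and the relations of pituitary hormone genes were tests chosen after the data had been seen. Nes, the nestin gene of radial glia, was higher after release than during brooding when adjusted over its list alone, at 12.8 ± 3.598 CPM (SD, n = 23) against 9.55 ± 1.67 (n = 21), as 1 of 16 radial glia and astroglia genes. Of 19 insulin, growth hormone and IGF genes, irs2b and igfbp3 were higher and ghra and igfbp6b lower over the list alone, with igfbp6b, a binding protein of insulin-like growth factors, at 25.7 ± 9.93 against 34.1 ± 5.91 CPM. Of 11 blood genes, sptb, the spectrin of red cells, was higher (18.1 ± 3.70 against 14.1 ± 2.83 CPM) and nt5c2l1 was lower (5.42 ± 4.11 against 11.1 ± 10.3 CPM). None of these genes passed over all loci (edgeR adjusted p = 0.186 at the lowest).

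Between R02 (n = 11) and B14 (n = 12), tp63 of stratified epithelium, at 1.89 ± 0.431 against 2.80 ± 0.854 CPM, and grhl3, at under 1 CPM, were lower among 12 skin and mouth epithelium genes when adjusted over the list alone, and neither passed over all loci. Nt5c2l1 was lower likewise among the blood genes, at 3.83 ± 2.09 against 13.7 ± 12.0 CPM.

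Pituitary hormone genes varied together between fish. Prl ranged from 0 to 557 CPM, gh1 from 0 to 513 and pomc from 0 to 1917 over 44 libraries. After group means of log2(CPM + 1) were removed, prl and gh1 had Pearson r = 0.961 and Spearman rho = 0.966, and prl and pomc r = 0.974 and rho = 0.968, each with a permutation p = 1e-05 within groups, the smallest that 100000 resamples can give, and the same Benjamini-Hochberg adjusted p = 1e-05 over the 2 relations computed. Without the 2 fish farthest from the median of prl, r was 0.955 and 0.970. The labels record no separate handling of the pituitary.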
